A study of Mus musculus with 6 samples.

How the data were processed

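Ovaries of female ICR mice, an outbred stock, were profiled by droplet single-cell RNA sequencing. The labels give 2 groups of 3 libraries, and each library is a separate mouse ovary taken from one side of the animal. PCOS-like mice, a model of polycystic ovary syndrome, received dehydroepiandrosterone (DHEA), an androgen precursor, at 6 mg per 100 g body weight under the skin in 0.1 mL daily for 20 days from the age of 25 days, and control mice received the vehicle (0 mg), sesame oil with ethanol. The spatial part of the study was not used here.

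The values deposited by the authors are count data: unique molecular identifier (UMI) counts per gene and cell barcode, made with Cell Ranger and mapped to mm10 per the submitters' processing notes, which name Seurat without a role. Versions of these tools are not given in the sources used here. Tested on the files, the counts were whole numbers for 32285 genes in 65641 barcodes, and every barcode held at least 500 UMIs. Library totals were 88125989, 86612160 and 78631249 UMIs in control mice 1 to 3 and 74949753, 84003526 and 83413750 in PCOS-like mice 1 to 3. Gene positions and transcript lengths came from GENCODE vM21 on GRCm38, the build that mm10 names.

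Cells were kept with at least 500 detected genes and at most 20% of UMIs from mitochondria-encoded genes. Scrublet, run in each library through scanpy 1.11.5, removed doublets at an expected rate of 0.008 per 1000 cells. Where its own threshold called under 0.5% of cells, the highest scores up to the expected rate were removed instead, which applied to control 1 and control 2, where it called 1 barcode each. Doublets made up 7.91%, 9.33% and 2.79% of the cells of control mice 1 to 3 and 3.64%, 2.43% and 4.12% of those of PCOS-like mice 1 to 3. The 53933 cells left numbered 9098, 10572 and 9044 in control mice and 7491, 8528 and 9200 in PCOS-like mice, with median depths of 7070.5, 5551.5, 7060.5, 8084, 8380.5 and 7461 UMIs in that order.

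Counts were scaled to the library, log-transformed and clipped at 10 standard deviations, and 3000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 (python-igraph 0.11.9) gave 31 clusters over all libraries without integration. Clusters were named from marker lists of 19 cell classes. A class was considered when at least 3 of its markers lay at least 1 log2 unit above the median cluster (with 10 CPM added) and were detected in at least 10% of the cluster's cells, and its score was the mean log2 ratio of its markers to the median cluster. The class with the highest score gave the name. A cluster stayed unnamed when the next class scored within 0.3 of it and the best class led by under 2 markers among the top 10 genes (those detected in at least 25% of cells), when another class held more of those leading genes, or when the median UMI count was under 0.333 of the library median with no marker of the class among them. A cluster with stromal markers overall and more theca markers among its leading genes was called stromal/theca-like. These naming thresholds were set with the data in hand, and 2 clusters stayed unnamed. Names carry the ending -like, since they rest on RNA alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

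The replicate was the mouse. Cell numbers per class were compared with the edgeR 4.0.16 quasi-likelihood test with total cells as library size, beside the exact two-sided permutation test of mean shares, which has 20 regroupings and cannot go below p = 0.10 with 3 mice against 3. UMI counts were summed per library and class, for classes with at least 20 cells in each library, and over all cells. These sums were compared with the edgeR quasi-likelihood test (TMM, filterByExpr, two-sided, robust) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values, within a class for genes and lists, with a threshold of 0.05. Lists of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, for lists with at least 5 measured genes after the markers of the class itself were left out. Beside it ran camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. The difference of the PCOS-like effect between granulosa-like and stromal-like cells was tested with limma on the difference of log2 CPM (prior count 2) within each library. DESeq2 1.42.0 was run as an alternative. A list's median is the median log2 fold change of its genes, PCOS-like over control.

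The 20 lists were steroidogenesis, cholesterol synthesis and uptake, androgen and glucocorticoid response genes, follicle growth genes of granulosa cells, ovulation and luteinization, apoptosis and p53 targets, cell cycle, collagens and extracellular matrix, TGF-beta response, inflammatory cytokines and NF-kB targets, interferon response, MHC class II and antigen presentation, glycolysis and hypoxia, nuclear genes of the mitochondrial respiratory chain, ER stress and unfolded protein response, lipid storage and fatty acid metabolism, angiogenesis, dissociation stress and immediate early genes, mitochondria-encoded transcripts, and cytosolic ribosomal proteins. Of their genes, 2 were absent from the files. The tests, groups, markers, lists and the rule for named genes were fixed before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 on the log2 CPM scale and no overlap of the groups, in granulosa-like, theca-like, luteal-like, stromal-like and all-cell sums, and 3 and 3 in other classes. It added up to 4 members of each list that passed its test, and genes always given, among them Cyp17a1, Cyp11a1, Star, Hsd3b1, Cyp19a1, Lhcgr, Fshr, Amh and Akr1c18. Markers of a class were not named within that class. Other genes named in the text were chosen after their values were seen.

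The tests were run on simulated data in which 200 genes of known fold were changed between 3 and 3 libraries. Each gene was given the spread that the trend in the real sums showed at its mean count. Genes were drawn independently, and libraries differed only in total count and the set changes. Recovery with spread that differs between genes of like count, or with a library that stands apart, was not measured. At 2-fold and 4-fold, edgeR recovered 39% and 90% of changed genes in granulosa-like sums (14789 genes tested, 4 false calls), 34% and 85% in T, NK or innate lymphoid-like sums (4471 genes, 4 false) and 33% and 83% over all cells (17488 genes, 5 false). DESeq2 recovered 46% and 88% with 19 false calls in granulosa-like sums, 24% and 78% with 4 false calls in T, NK or innate lymphoid-like sums, and 38% and 86% with 29 false calls over all cells. In simulated granulosa-like sums with independent genes, an interferon list lowered by 0.5 log2 units was recovered by camera at the preset correlation with 0 false calls, was not recovered with an estimated correlation, and was recovered by fry with 1 false call. Genes of the real lists had estimated correlations of up to 0.825, so these counts of false calls do not carry over to them. The limma test of the difference recovered 172 of 200 genes raised by 2 log2 units (12589 tested, 9 false calls), and the edgeR test of cell numbers recovered a theca-like class raised by 3 log2 units, with 0 false calls among 16 classes.

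Alternatives fixed in advance were Leiden resolution 0.5, clusters found within each library, doublets kept, a stricter cell filter (1000 genes, 10% mitochondrial), DESeq2 size factors, the DESeq2 test, 10 CPM in 3 libraries or no filter on low counts, a prior count of 0.5, a replicate block, an estimated correlation, fry, shares outside granulosa-like cells, TMM on cell numbers, and each library left out in turn. Chosen after seeing the data were doublets removed at the expected rate in every library, unnamed clusters left out, and a loess trend (span 0.5) on transcript length removed from each library. List medians with that trend removed are of differences between group means of log2 CPM, where the other list medians are of edgeR fold changes.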

Results

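Single-cell RNA profiles were collected from 6 mouse ovaries, 3 from vehicle-injected control mice and 3 from PCOS-like mice injected with DHEA for 20 days. The libraries held 78631249 to 88125989 UMIs in control mice and 74949753 to 84003526 in PCOS-like mice. After filtering, 53933 cells remained, with median depths of 5551.5 to 7070.5 UMIs per cell in control libraries and 7461 to 8380.5 in PCOS-like libraries. Clustering gave 31 clusters, of which 29 fell into 15 named classes, and genes were compared in the 8 classes with at least 20 cells in every library and over all cells.

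The first comparison asked whether the cell make-up of the ovary differed between the groups. Theca-like cells, the layer around follicles that makes androgens, held 9.47% ± 0.57 (SD, n = 3) of cells in PCOS-like ovaries and 5.84% ± 1.80 (SD, n = 3) in control ovaries, and all 3 PCOS-like values lay above all 3 control values. Stromal/theca-like cells showed the same ordering, at 11.0% ± 1.93 (SD, n = 3) and 7.73% ± 1.91 (SD, n = 3). The margin was narrow, with 9.75% in PCOS-like 3 and 9.59% in control 3. That ordering did not hold with unnamed cells left out of the total. Oocyte-like cells held 0.0310% ± 0.00400 (SD, n = 3) in PCOS-like and 0.399% ± 0.433 (SD, n = 3) in control ovaries, or 2, 3 and 3 cells against 22, 94 and 6. Granulosa-like cells, which surround and support the oocyte, held 40.4% ± 11.2 (SD, n = 3) in PCOS-like and 33.1% ± 8.18 (SD, n = 3) in control ovaries. None of the 16 shares passed the edgeR quasi-likelihood test. The log2 differences of theca-like, stromal/theca-like and oocyte-like shares were 0.70 (SE 0.397), 0.51 (SE 0.383) and -3.61 (SE 1.03), with edgeR adjusted p = 0.724, 0.737 and 0.21. The exact two-sided permutation p was 0.1 for each of these classes, the lowest that 3 mice against 3 allow, and 0.6 for granulosa-like cells. Without control 3 the oocyte-like share passed, with a log2 difference of -4.11 and an edgeR adjusted p of 0.0421, and without control 2 the difference was -2.24 with an edgeR adjusted p of 0.369.

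Luteal-like cells, the progesterone-making cells left after ovulation, varied most between mice. They held 3.84%, 28.6% and 3.32% of cells in control mice 1 to 3 and 0.0667%, 5.25% and 15.5% in PCOS-like mice 1 to 3, with a log2 difference of -0.78 (SE 1.64), an edgeR adjusted p of 0.871 and an exact permutation p of 0.7. PCOS-like mouse 1 gave 5 luteal-like cells of 7491, for which the exact 95% interval of 0.0217% to 0.156% covers counting error only. Different clusters held the class in different mice: 2509 of the 2617 cells of 1 luteal-like cluster came from control 2, 1182 of the 1184 cells of another from PCOS-like 3, and 103 of the 104 cells of another from control 3. Granulosa-like cells were also split by mouse, since PCOS-like 1 gave 1179 of the 1555 cells of 1 cluster and 1498 of the 3098 cells of another, and control 1 gave 1100 of the 1385 cells of a cluster marked by Cyp19a1, the aromatase gene. Unnamed cells held 23.3%, 10.6% and 9.05% in control mice and 0.214%, 6.41% and 4.51% in PCOS-like mice, also without overlap of the groups (log2 difference -1.95, edgeR adjusted p = 0.724, exact permutation p = 0.1). With these cells left out of the total, an alternative chosen after seeing the data, the log2 differences were 0.55 for theca-like, 0.35 for stromal/theca-like and 0.09 for granulosa-like shares (edgeR adjusted p = 0.781, 0.781 and 0.97). The stromal/theca-like share of control 3 then lay above that of PCOS-like 3, while theca-like shares of the groups still did not overlap. The unnamed cells lay in 2 clusters, with 1521 of the 1545 cells of the smaller from control 1 and a median of 1041 UMIs per cell in the larger. In the smaller, oocyte markers scored 1.83 beside 1.99 for granulosa markers, and its cells are not counted as oocyte-like. The remaining classes had mean shares in control and PCOS-like ovaries of 13.4% and 14.8% for stromal-like cells, 4.16% and 4.70% for smooth muscle and pericyte-like cells, 4.01% and 3.01% for blood endothelial-like cells, 2.24% and 2.34% for macrophage or monocyte-like cells, and 1.40% and 1.62% for T, NK or innate lymphoid-like cells. B or plasma-like cells held 0.615% and 0.957%, neutrophil-like cells 0.217% and 0.479%, lymphatic endothelial-like cells 0.260% and 0.286%, surface epithelial or mesothelial-like cells 0.189% and 0.132%, and dendritic-like cells 0.152% and 0.102%. Median depth over all cells was higher in PCOS-like libraries, and depth can affect how many barcodes pass a filter on detected genes. Within granulosa-like cells it was not higher, at 10901, 9578 and 9208 UMIs in control and 9437.5, 9869 and 8180 in PCOS-like mice. Luteal-like medians were higher in PCOS-like mice (13409, 13030.5 and 9247.5) than in control mice (4342, 3541.5 and 2338). Unnamed cells, more frequent in control mice, had control medians of 1515, 1885 and 957. Depth over all cells thus also depends on the classes present.

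**Figure D1:**
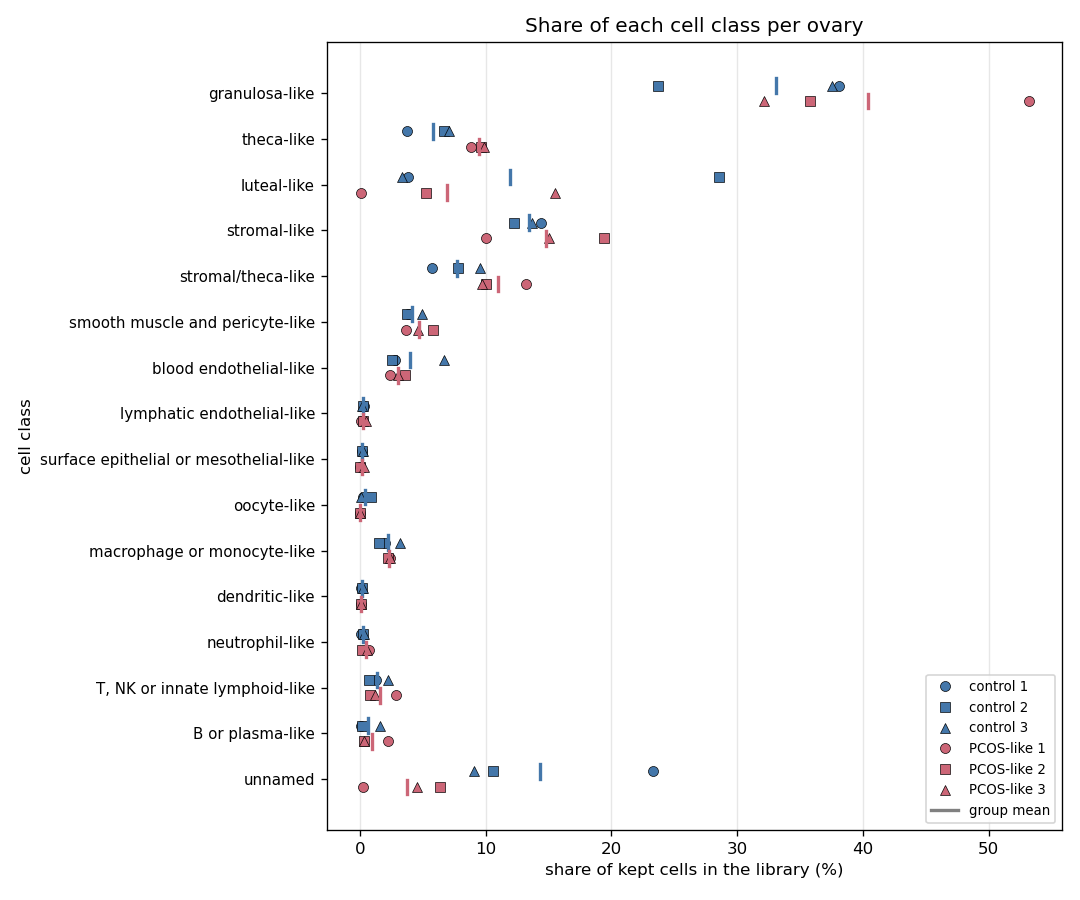
Share of kept cells (%, horizontal axis) in each cell class (vertical axis), with 1 point per ovary (circle, square and triangle for mice 1, 2 and 3), blue for control and red for PCOS-like, and a bar at each group mean. Theca-like shares of the 3 PCOS-like ovaries lie between 8.82% and 9.91%, above the 3 control ovaries at 3.77% to 7.07%, while luteal-like shares run from 0.0667% to 28.6% over all 6.

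The next question was whether genes of the steroid pathway and of follicle growth differed over the whole ovary, since DHEA is an androgen precursor. Cyp17a1 makes androgen precursors in theca cells. It stood at 513, 676 and 328 CPM (UMI counts scaled to the size of each sum) in control mice and 298, 689 and 39.8 in PCOS-like mice. PCOS-like 3, with the highest theca-like share of the 6 ovaries (9.91%), gave the lowest Cyp17a1 value. A higher share of theca-like cells thus did not go with more Cyp17a1 in that mouse. Star, which carries cholesterol into mitochondria, ranged from 166 to 204 CPM in control mice and gave 17.2, 146 and 306 in PCOS-like mice, and Hsd3b1 gave 648 ± 146 and 854 ± 392 CPM (SD, n = 3 each). The side-chain cleavage gene Cyp11a1 stood at 1083 ± 771 CPM in control and 1405 ± 1132 in PCOS-like mice (SD, n = 3 each). Akr1c18, which breaks down progesterone in old luteal cells, stood at 71.0, 690 and 239 CPM in control mice and 1.55, 138 and 72.3 in PCOS-like mice. PCOS-like 1 was lowest in Akr1c18 and Star as it was in luteal-like cells. Amh, the anti-Müllerian hormone gene of small growing follicles, stood at 116, 101 and 93.6 CPM in control mice and 232, 73.3 and 73.9 in PCOS-like mice. The FSH receptor gene Fshr gave 18.4 ± 1.43 and 23.4 ± 13.7 CPM, the LH receptor gene Lhcgr 122 ± 44.5 and 106 ± 61.5, and Cyp19a1 43.1 ± 43.6 and 18.5 ± 10.8 (control and PCOS-like, SD, n = 3 each). None of these 9 genes passed the edgeR quasi-likelihood test over all cells, with adjusted p from 0.696 for Akr1c18 to 0.916 for Star.

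**Figure D2:**
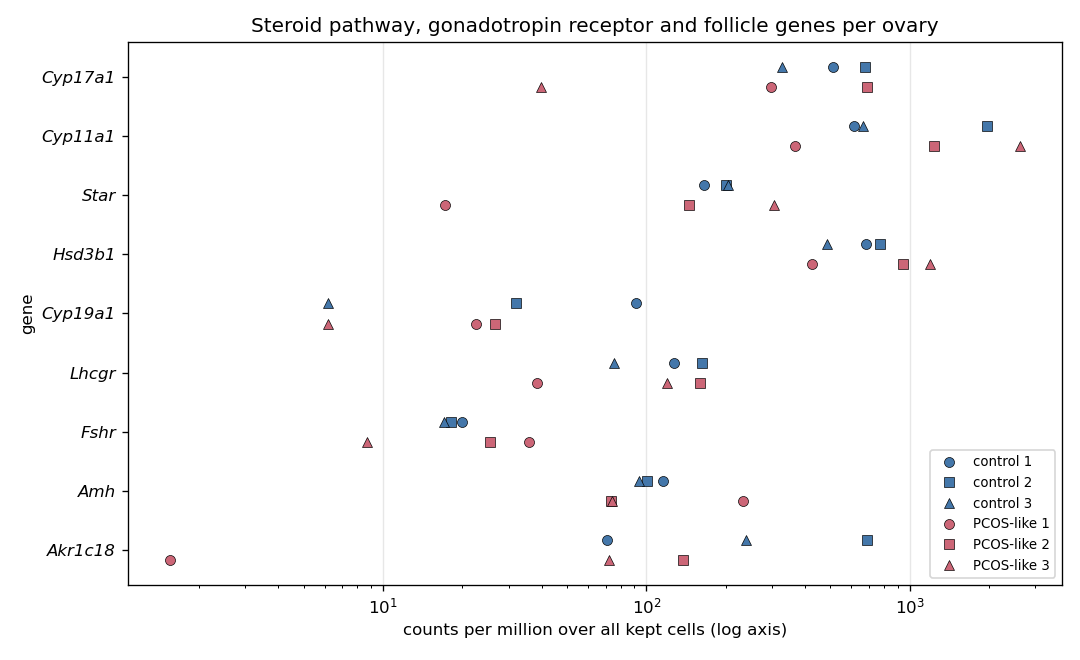
CPM over all kept cells (log axis, horizontal) for 9 genes of the steroid pathway, gonadotropin receptors and follicles (vertical axis), with 1 point per ovary (circle, square and triangle for mice 1, 2 and 3), blue for control and red for PCOS-like. PCOS-like 1 gave the lowest Star (17.2) and Akr1c18 (1.55) values of the 6 ovaries and the highest Amh value (232).

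Over all cells, the oocyte genes Nlrp5, Zp2 and Ooep stood lower in each PCOS-like mouse than in any control mouse. Nlrp5, a maternal-effect gene of the egg, stood at 11.8, 4.27 and 7.44 CPM in control mice and 1.59, 1.51 and 1.21 in PCOS-like mice, a log2 difference of -2.44 (SE 0.371). Zp2, a gene of the zona pellucida, stood at 8.61 ± 4.71 CPM in control and 1.42 ± 0.231 in PCOS-like mice (SD, n = 3 each), and Ooep at 66.7, 19.0 and 23.3 and 7.08, 3.55 and 3.67 CPM. The edgeR quasi-likelihood test called 0 of 17460 genes, with 904 at an unadjusted p under 0.05, and gave these 3 genes adjusted p = 0.696 each. DESeq2 called 46 genes, 7 higher and 39 lower, and 4 of the 9 oocyte markers (Zp2, Ooep, Dppa3 and Figla) were among the 39. Its adjusted p was 1.33e-06 for Nlrp5, 1.9e-06 for Zp2 and 6.49e-06 for Ooep. Of the DESeq2 calls in simulated all-cell sums, 29 of 153 were false, more than a threshold of 0.05 allows. Among control mice Nlrp5 did not follow the number of oocyte-like cells, at 11.8 CPM with 22 cells, 4.27 with 94 and 7.44 with 6. That number leaves out an unnamed cluster with Ooep and Dppa3 among its leading genes, 1521 of whose 1545 cells came from control 1. The groups did not overlap in 11.6% of genes, where chance gives 10%. Leaving out any 1 library left the edgeR count at 0.

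Cox7b, a subunit of cytochrome c oxidase on chromosome X (mm10, 106015700 to 106022450, ENSMUSG00000031231), was followed over all sums. All 3 PCOS-like libraries lay above all 3 control libraries in each of the 9 sums, with log2 differences of 0.85 to 1.37. Over all cells it gave 360, 381 and 469 CPM in control mice and 1171, 846 and 660 in PCOS-like mice, a log2 difference of 1.15 (SE 0.254, edgeR adjusted p = 0.696). The edgeR test called Cox7b in 0 of the 9 sums and DESeq2 in 6. All sums come from the same 6 mice, and the all-cell sum includes the cells of the classes. Counts of sums, here and for other genes and lists, are therefore not independent replications. Retsat, a retinol saturase gene on chromosome 6 (mm10, 72598475 to 72608425, ENSMUSG00000056666), was higher in all 3 PCOS-like mice than in any control in 4 of the 8 sums where it was tested, with DESeq2 calls in 2 and edgeR calls in 0. Cox7b, Retsat, Nlrp5, Zp2 and Ooep were chosen after their values were seen.

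Across cell classes, nuclear genes of the mitochondrial respiratory chain rose together in PCOS-like ovaries. The list passed camera in all 8 classes and over all cells, with median log2 differences from 0.28 in macrophage or monocyte-like cells to 0.49 in smooth muscle and pericyte-like cells, and camera adjusted p from 2.1e-08 to 0.000102 (adjusted p = 0.577 to 0.988 with an estimated correlation). All 20 of its genes were higher in granulosa-like cells and over all cells, among them Ndufa4 (464 ± 98.0 to 728 ± 219 CPM over all cells, SD, n = 3 each) and Uqcrb (352 ± 71.3 to 577 ± 233). Cytosolic ribosomal protein genes, which build the translation machinery, rose in 7 classes and over all cells, with medians of 0.30 to 0.43 and camera adjusted p from 7.11e-08 to 0.00377, and did not pass in stromal/theca-like cells (camera adjusted p = 0.125). With an estimated correlation neither list passed anywhere, with adjusted p = 0.577 to 0.988 for each. No call of any of the 20 lists held with an estimated correlation, or in fry. Counts of single genes gave 0 changed members of either list, adjusted over the list alone and over all genes tested. With the transcript length trend removed, an alternative chosen after seeing the data, ribosomal genes passed in 4 of their 8 sums, and the calls ended in theca-like (median 0.06), stromal-like (0.11), smooth muscle and pericyte-like (0.10) and macrophage or monocyte-like cells (0.07). Respiratory chain genes passed in 6 of 9 sums, and the calls ended in theca-like (median 0.07), stromal/theca-like (0.11) and macrophage or monocyte-like cells (0.12).

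PCOS-like 1 stood apart in this pattern. Its respiratory chain median over all cells was 0.85 above the control mean, beside 0.09 and 0.30 in PCOS-like 2 and 3 and 0.03, 0.13 and -0.15 in control mice. Without PCOS-like 1 the list passed camera in all 9 sums, with medians of 0.14 to 0.28, and camera adjusted p of at most 0.0115. Without control 3 the macrophage or monocyte-like median was 0.16, and without control 2 it was 0.44. Ribosomal protein genes were no longer called without PCOS-like 1 in theca-like (median 0.05, camera adjusted p = 0.317), stromal-like (0.05, 0.145) and macrophage or monocyte-like cells (0.08, 0.198), nor in theca-like cells without control 2 (0.23, 0.144). Where still called without PCOS-like 1, ribosomal medians were 0.15 in granulosa-like, 0.16 in smooth muscle and pericyte-like, 0.30 in blood endothelial-like and 0.20 in T, NK or innate lymphoid-like cells and 0.14 over all cells. Transcript length moved with the same mice. Across the 17443 genes with a length over all cells, which are not independent replicates, Spearman's correlation of the log2 fold change with transcript length was -0.412, and it was -0.385 to -0.537 in the 8 classes. The same correlation for the deviation of PCOS-like 1 over all cells was -0.459, against 0.257 and -0.098 in PCOS-like 2 and 3 and 0.218, 0.198 and 0.314 in control mice. Neat1, a long RNA kept in the nucleus, was lowest in PCOS-like 1 in all 9 sums, as were the nuclear RNAs Kcnq1ot1 in 8, Malat1 in 7 and Meg3 in 0.

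**Figure D3:**
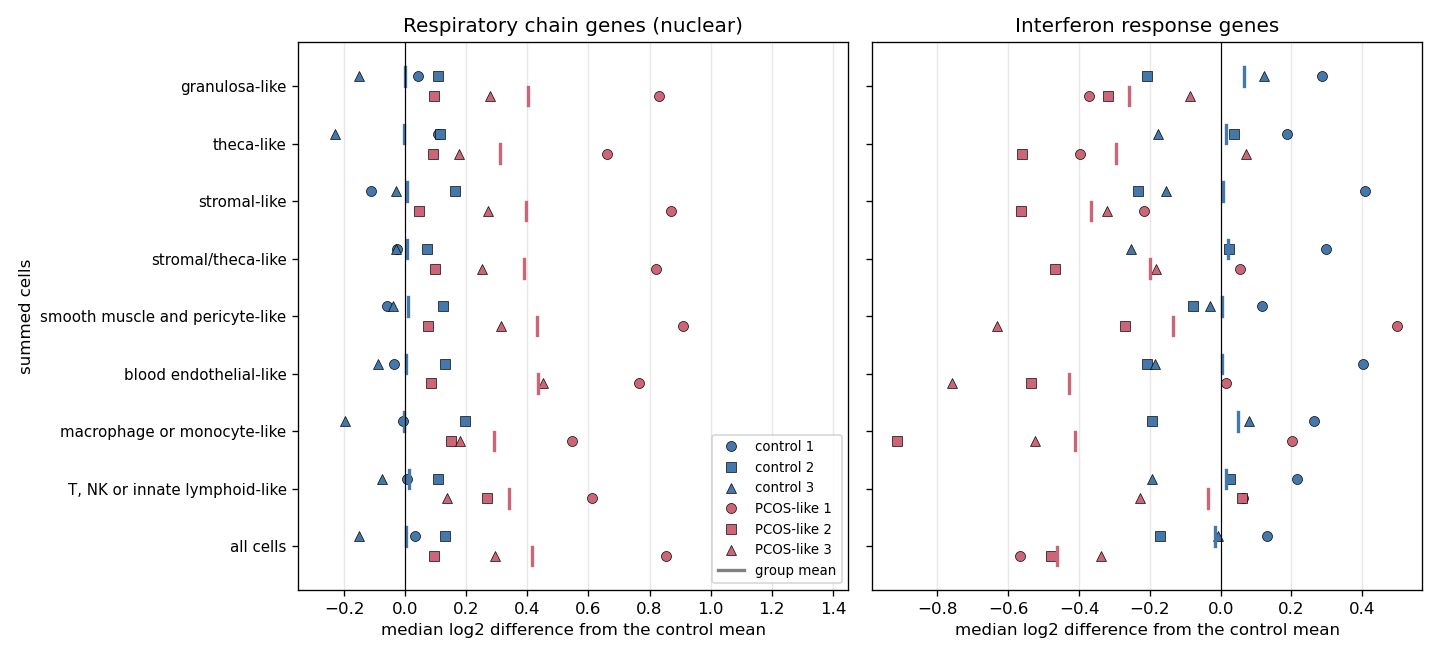
Median log2 difference of each library from the control mean (horizontal axes) for nuclear respiratory chain genes (left) and interferon response genes (right) in 8 cell classes and over all cells (vertical axis), with 1 point per ovary (circle, square and triangle for mice 1, 2 and 3), blue for control and red for PCOS-like, and a bar at each group mean. Over all cells the respiratory chain medians are 0.85, 0.09 and 0.30 in PCOS-like 1 to 3, and the interferon medians are -0.57, -0.48 and -0.34.

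**Figure D4:**
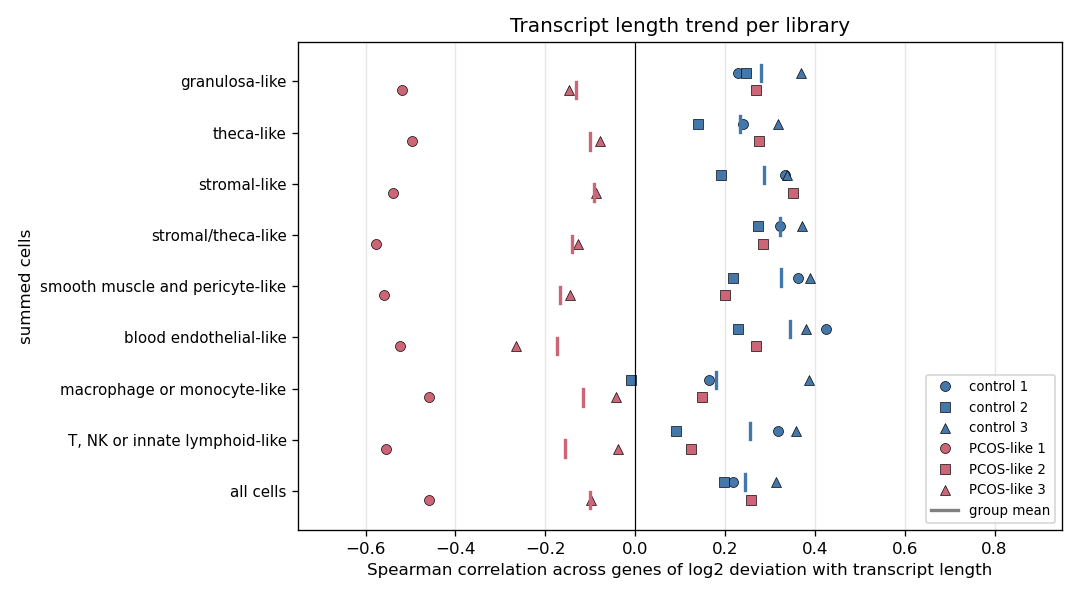
Spearman correlation across genes (horizontal axis) between transcript length and the log2 deviation of a library from the mean of the libraries, in 8 cell classes and over all cells (vertical axis), with 1 point per ovary (circle, square and triangle for mice 1, 2 and 3), blue for control and red for PCOS-like, and a bar at each group mean. PCOS-like 1 lies between -0.458 and -0.578 in the 9 sums, below every other library.

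Interferon response genes fell in PCOS-like ovaries in 5 classes and over all cells. The list's median log2 difference was -0.39 over all cells (camera adjusted p = 1.45e-05), where 16 of its 19 measured genes were lower, and -0.45 in blood endothelial-like, -0.34 in macrophage or monocyte-like, -0.29 in stromal-like, -0.27 in theca-like and -0.22 in smooth muscle and pericyte-like cells. With an estimated correlation the adjusted p was 0.596 over all cells and at least 0.639 in these classes. Over all cells Ifi44 stood at 7.18 ± 2.02 CPM in control and 3.56 ± 0.914 in PCOS-like mice, Rsad2 at 8.31 ± 1.88 and 4.50 ± 0.939, and Usp18, a brake on interferon signalling, at 6.23 ± 0.541 and 4.02 ± 0.579 (SD, n = 3 each), and in each of these the groups did not overlap. Adjusted over the list alone, 5 members were lower over the 9 sums, among them 1 in blood endothelial-like and 3 in macrophage or monocyte-like cells. Over all genes tested the count was 0. The call over all cells stayed without any 1 library. PCOS-like 1 weakened the fall in several classes. Without it the median was -1.16 in macrophage or monocyte-like, -0.68 in blood endothelial-like, -0.52 in stromal-like and -0.42 in smooth muscle and pericyte-like cells. In theca-like cells it was -0.24. Ifitm1, outside the list and chosen after its values were seen, was higher over all cells by DESeq2 (log2 0.84, adjusted p = 0.0146).

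Granulosa-like cells showed a rise of cell cycle genes beside the respiratory chain and ribosomal lists. The cell cycle median was 0.22 (camera adjusted p = 0.00677, and adjusted p = 0.89 with an estimated correlation, as for the respiratory chain and ribosomal lists), with 16 of 20 genes higher. Birc5, which acts in chromosome segregation, stood at 71.0 ± 6.54 CPM in control and 117 ± 45.1 in PCOS-like mice, Ube2c at 122 ± 13.4 and 192 ± 62.8, and the mitotic kinase gene Cdk1 at 33.3 ± 3.29 and 49.6 ± 14.6 (SD, n = 3 each). The respiratory chain median was 0.44 (camera adjusted p = 2.23e-06), with Cox5a at 310 ± 81.6 and 480 ± 128 CPM, and the ribosomal median 0.35 (camera adjusted p = 6.48e-05), with Rps2 at 2459 ± 220 and 3387 ± 1104 CPM (SD, n = 3 each). Lhcgr, which granulosa cells gain late in follicle growth, stood at 113, 75.6 and 7.12 CPM in control mice and 4.56, 19.6 and 12.3 in PCOS-like mice, a log2 difference of -2.43 (SE 1.03, edgeR adjusted p = 0.653). Sums of this class mix clusters whose sizes differed between mice. The cluster marked by Cyp19a1 held 1100, 214 and 7 cells in control mice and 6, 52 and 6 in PCOS-like mice. Another, led by genes such as Top2a and Mki67, held 549, 313 and 557 in control and 765, 425 and 537 in PCOS-like mice. Whether Lhcgr or cell cycle genes differed within a cluster was not tested. Akr1c18, a luteal gene, gave 10.4, 40.4 and 101 CPM in the control sums of this class and 1.11, 47.9 and 11.5 in the PCOS-like sums. In this class edgeR called 0 of 14784 genes, with 893 at an unadjusted p under 0.05, while DESeq2 called 12, among them Cox7b (adjusted p = 0.0169) and Retsat (adjusted p = 0.000555). Of the DESeq2 calls in simulated sums of this class, 19 of 153 were false. Retsat stood at 7.23 ± 0.624 CPM in control and 16.4 ± 2.84 in PCOS-like mice (SD, n = 3 each). Without control 2 or without control 3 edgeR called 1 gene, and the cell cycle list was no longer called without PCOS-like 3 (median 0.19, camera adjusted p = 0.185) and had a median of 0.37 without PCOS-like 2. The groups did not overlap in 12.4% of genes, where chance gives 10%.

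In theca-like cells the interferon and TGF-beta response lists fell, and respiratory chain, ribosomal and mitochondria-encoded transcripts rose, though 4 of these 5 calls (all but interferon) ended when the transcript length trend was removed. The TGF-beta median was -0.21 (camera adjusted p = 0.046, and adjusted p = 0.776 with an estimated correlation), with Ccn1, a matrix protein induced by TGF-beta, at 241 ± 42.8 CPM in control and 175 ± 60.3 in PCOS-like mice and Tgfb1 at 16.3 ± 1.76 and 11.7 ± 4.52 (SD, n = 3 each). Among interferon response genes Gbp3 had a log2 difference of -0.81, while Bst2 stood at 422 ± 43.3 CPM in control and 658 ± 345 in PCOS-like mice (SD, n = 3 each). Mitochondria-encoded transcripts had a median of 0.25 (camera adjusted p = 0.046, and adjusted p = 0.776 with an estimated correlation), with mt-Cytb at 8000 ± 1501 and 10470 ± 2175 CPM (SD, n = 3 each). For each list called in this class the adjusted p was 0.776 with an estimated correlation. Among steroid genes, Lhcgr stood at 727 ± 296 and 398 ± 217 CPM (log2 difference -0.87, SE 0.456, edgeR adjusted p = 0.778), Star at 730, 471 and 256 in control mice and 110, 414 and 899 in PCOS-like mice, and Hsd3b1 at 2744 ± 520 and 3426 ± 1081 (SD, n = 3 each). The edgeR test called 0 of 12168 genes, with 604 at an unadjusted p under 0.05, and DESeq2 called 2, Kcnk1 higher (log2 2.02) and the matrix gene Postn lower (log2 -1.61), both named after their values were seen. The groups did not overlap in 11.3% of genes, where chance gives 10%. The TGF-beta list was lost without control 1 (camera adjusted p = 0.182), control 3 (0.0643), PCOS-like 1 (0.0568) and PCOS-like 3 (0.775), and its median was -0.33 without PCOS-like 2. Mitochondria-encoded transcripts were lost without control 1 (camera adjusted p = 0.241), control 3 (0.394), PCOS-like 2 (0.0985) and PCOS-like 3 (0.615), and had a median of 0.51 without control 2. The interferon list was lost without control 1 (camera adjusted p = 0.139), control 2 (0.15) and PCOS-like 2 (0.412), and its median was -0.51 without PCOS-like 3, while the edgeR count was 1 without control 2. The TGF-beta call also ended with the length trend removed (median -0.12), with doublets kept (-0.18), under the stricter cell filter (-0.17), at Leiden resolution 0.5 (-0.18) and with clusters found per library (-0.19). Under the same 5 alternatives the mitochondria-encoded call ended, with medians of -0.01, 0.22, 0.24, 0.24 and 0.16, and the interferon call ended under the stricter cell filter (-0.26).

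Stromal-like cells, the connective tissue of the ovary, showed lower interferon genes and higher respiratory chain and ribosomal genes. Stat2 stood at 24.2 ± 5.35 CPM in control and 13.7 ± 4.25 in PCOS-like mice, Ifit2 at 18.8 ± 2.72 and 10.7 ± 3.71, and Rsad2 at 11.4 ± 4.63 and 4.84 ± 2.25 (SD, n = 3 each), with no overlap of the groups in any of these. The interferon median was -0.29 (camera adjusted p = 0.00168), the respiratory chain median 0.46 (camera adjusted p = 1.14e-06) and the ribosomal median 0.42 (camera adjusted p = 0.000198). With an estimated correlation the adjusted p was 0.988 for these lists. The edgeR test called 0 of 12966 genes, with 594 at an unadjusted p under 0.05, and DESeq2 called 4, of which Saa3, an acute-phase gene named after its values were seen, was lower (log2 -3.70, adjusted p = 1.01e-05). No overlap of the groups was seen in 11.1% of genes, where chance gives 10%. The interferon list was lost without control 1 (median -0.04, camera adjusted p = 0.176) and PCOS-like 2 (-0.17, 0.25), and its median was -0.44, -0.45 and -0.52 without control 2, control 3 and PCOS-like 1, while the edgeR count was 1 without control 2, control 3 or PCOS-like 3.

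Of the 8 classes, stromal/theca-like cells gave the most genes by DESeq2, 37, of which 33 were higher in PCOS-like ovaries. They included Areg (log2 1.61, adjusted p = 0.0116) and Ereg (log2 1.52, adjusted p = 0.0111), which encode the EGF-like ligands of the ovulatory response, Tnfaip6 (log2 1.16, adjusted p = 0.00131), which stabilises the matrix around the ovulated egg, and Cebpb (log2 1.20, adjusted p = 0.0207), a regulator of luteinization, all chosen after their values were seen. Of interferon-inducible genes, also chosen so, DESeq2 called Ifi202b (log2 1.73), Ifi211 (1.47) and Ifitm1 (1.09) higher and Mndal (-1.14) lower. Areg, Ereg, Tnfaip6 and Cebpb are members of the ovulation list, in which 4 genes were higher adjusted over the list alone with edgeR and 0 over all genes tested, and which did not pass camera (median 0.28, adjusted p = 0.106). The steroid enzyme gene Hsd3b1 stood at 81.8 ± 18.0 CPM in control and 132 ± 5.35 in PCOS-like mice (SD, n = 3 each, log2 0.69, edgeR adjusted p = 0.424), with no overlap of the groups. The respiratory chain list passed (median 0.45, camera adjusted p = 0.000102, and adjusted p = 0.817 with an estimated correlation). The edgeR test called 0 of 12284 genes, with 1378 at an unadjusted p under 0.05 and the smallest adjusted p, 0.198, for Enho, and the groups did not overlap in 18.3% of genes, where chance gives 10%. Without PCOS-like 2 edgeR called 36 genes, without PCOS-like 1 it called 5, and without control 2 or PCOS-like 3 it called 1. Lists called rose from 1 to 6 without control 1, 3 without control 3 and 4 without PCOS-like 1 or PCOS-like 3.

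In smooth muscle and pericyte-like cells, the contractile cells of vessels and follicle walls, 1 gene passed, and it was the only call of the edgeR gene tests. Grk3, a G protein-coupled receptor kinase that quiets activated receptors (chromosome 5, mm10, 112910482 to 113015791, ENSMUSG00000042249), fell from 51.3 ± 3.34 CPM in control to 17.5 ± 3.73 in PCOS-like mice (SD, n = 3 each). Its log2 difference was -1.55 (SE 0.221), with an edgeR adjusted p of 0.0372 and a DESeq2 adjusted p of 0.00127, and the values were 54.5, 47.8 and 51.5 CPM in control mice and 19.1, 20.1 and 13.2 in PCOS-like mice. In other sums Grk3 was not called. Counting the called class, every PCOS-like library lay below every control library in 4 of the 7 sums where it was tested, with log2 differences of -1.55 to -0.06. Gene by gene, edgeR called 1 of 10230 genes, with 881 at an unadjusted p under 0.05, and DESeq2 called 4. They included Cd74, the MHC class II chaperone gene, at 39.4 ± 23.5 and 9.61 ± 3.01 CPM (SD, n = 3 each, DESeq2 adjusted p = 0.00286, chosen after its values were seen). The call of Grk3 was lost without control 1 (edgeR adjusted p = 0.217), control 2 (0.122), control 3 (0.203), PCOS-like 2 (0.0508) and PCOS-like 3 (0.178), while its log2 difference stayed between -1.38 and -1.71. It was also lost with doublets kept (edgeR adjusted p = 0.0587), at Leiden resolution 0.5 (0.645) and with clusters found per library (0.946), in a range over all alternatives of 3.3e-06 to 0.946. No overlap of the groups was seen in 16.2% of genes, where chance gives 10%.

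Angiogenesis genes fell in these cells as a list (median -0.25, camera adjusted p = 0.0102, and adjusted p = 0.608 with an estimated correlation), with all 11 measured genes lower. Pgf, a growth factor of vessels, stood at 57.4 ± 5.92 CPM in control and 40.6 ± 5.40 in PCOS-like mice, and Angpt1, which steadies vessels, at 85.5 ± 9.49 and 61.1 ± 13.5 (SD, n = 3 each). Respiratory chain (median 0.49, camera adjusted p = 2.1e-08), ribosomal (0.40, 4.14e-06), cell cycle (0.31, 0.0348) and mitochondria-encoded genes (0.23, 0.0348) rose, and interferon genes fell (-0.22, 0.0218). With an estimated correlation the adjusted p was 0.639 for these 5 lists. Cdk1 stood at 7.61 ± 1.40 and 15.8 ± 6.32 CPM, Ndufa4 at 345 ± 46.4 and 611 ± 164, and Stat2 at 17.4 ± 0.414 and 8.82 ± 3.76 (SD, n = 3 each). The angiogenesis median was -0.39 without control 2 and without PCOS-like 2. The cell cycle list was lost without control 1 (camera adjusted p = 0.211), PCOS-like 1 (0.163) and PCOS-like 2 (0.529), with medians of 0.47 and 0.51 without control 3 and PCOS-like 3. The mitochondria-encoded list was lost without control 1 (camera adjusted p = 0.202), control 3 (0.146), PCOS-like 2 (0.197) and PCOS-like 3 (0.234), with a median of 0.38 without control 2. The interferon list was lost without control 1 (camera adjusted p = 0.0651), PCOS-like 2 (0.197) and PCOS-like 3 (0.513), with medians of -0.37, -0.11 and -0.42 without control 2, control 3 and PCOS-like 1. Clusters found per library ended the angiogenesis (median -0.20) and interferon (-0.11) calls and turned the cell cycle median to -0.17, and Leiden resolution 0.5 ended the angiogenesis call (-0.26). The stricter cell filter ended the cell cycle (0.23) and mitochondria-encoded (0.23) calls, and removing the length trend turned the mitochondria-encoded median to -0.12.

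Blood endothelial-like cells showed the lowest interferon median, and the glycolysis list passed as higher and the angiogenesis list as lower. The 3 measured markers of macrophages and of T or NK cells had a median log2 difference of -0.72 in the same sums, below the interferon median. Ifit3 stood at 51.2 ± 20.1 CPM in control and 16.0 ± 7.88 in PCOS-like mice and Ifi44 at 129 ± 51.0 and 74.6 ± 11.0 (SD, n = 3 each), in a list with a median of -0.45 (camera adjusted p = 3.04e-05, and adjusted p = 0.739 with an estimated correlation). Of the 16 glycolysis genes (median 0.39, camera adjusted p = 0.0489, and adjusted p = 0.733 with an estimated correlation), 9 had values above and 7 below control, such as Pfkp (log2 -0.50) and Pfkfb3 (-0.35). Of these genes 4 were higher adjusted over the list alone and 0 over all genes tested. They were Hk2, which starts glucose use, at 7.27 ± 0.694 and 17.0 ± 8.14 CPM, Pgk1 at 65.2 ± 8.34 and 107 ± 23.6, Gapdh at 530 ± 15.8 and 860 ± 293, and Eno1 at 78.8 ± 8.86 and 122 ± 18.7 (SD, n = 3 each). The angiogenesis median was -0.30 (camera adjusted p = 0.0489, and adjusted p = 0.733 with an estimated correlation), with Nrp2, a co-receptor of vascular growth factors, at 220 ± 15.1 and 148 ± 41.9 CPM and the angiopoietin receptor gene Tek at 177 ± 2.23 and 140 ± 23.1 (SD, n = 3 each). Respiratory chain and ribosomal medians were 0.45 (camera adjusted p = 3.82e-08) and 0.40 (camera adjusted p = 7.11e-08). The adjusted p with an estimated correlation was 0.733 for these 4 lists. Tested singly, edgeR called 0 of 9619 genes, with 893 at an unadjusted p under 0.05, and DESeq2 called 2, Cox7b (adjusted p = 0.00014) and Ifi203, an interferon-inducible gene (log2 -1.42), both chosen after their values were seen. Glycolysis was lost without control 2 (camera adjusted p = 0.0784), control 3 (0.0766), PCOS-like 1 (0.0554) and PCOS-like 3 (0.0618). Angiogenesis was lost without control 2 (median -0.17, camera adjusted p = 0.0784), PCOS-like 2 (-0.16, 0.0664) and PCOS-like 3 (-0.10, 0.0769), and its median was -0.18 without control 1. The interferon median was -0.19 without control 1 and -0.68 without PCOS-like 1, and the respiratory chain median was 0.28 without PCOS-like 1. Here edgeR called 1 gene without control 1 and 3 without control 2. The glycolysis call ended under the stricter cell filter (median 0.38), with doublets kept (0.39) or set at the expected rate (0.38) and with clusters found per library (-0.03), and its median was 0.09 with the length trend removed. The angiogenesis call ended with doublets kept (-0.18) or set at the expected rate (-0.26) and with clusters found per library (-0.19). No overlap of the groups was seen in 16.2% of genes, where chance gives 10%.

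Macrophage or monocyte-like cells had lower interferon genes and higher cell cycle, respiratory chain and ribosomal genes. Ifit2, an antiviral gene induced by interferon, stood at 45.9, 55.8 and 102 CPM in control mice and 29.5, 15.8 and 11.9 in PCOS-like mice (log2 -1.90, SE 0.385, edgeR adjusted p = 0.905, DESeq2 adjusted p = 0.0326), and Stat2 at 33.1 ± 8.58 and 13.1 ± 2.39 (SD, n = 3 each). The list medians were -0.34 for interferon (camera adjusted p = 0.00112), 0.34 for cell cycle (camera adjusted p = 0.00119), 0.28 for respiratory chain (camera adjusted p = 8.06e-05) and 0.31 for ribosomal genes (camera adjusted p = 0.00119). Collagen genes (median 0.22, camera adjusted p = 0.00237) and follicle growth genes (median 0.27, camera adjusted p = 0.0434) also rose, though stromal and granulosa cells are their known sources. For these 6 lists the adjusted p was 0.679 with an estimated correlation. Amh stood at 16.5, 4.73 and 12.7 CPM in control and 99.2, 14.9 and 8.47 in PCOS-like sums of this class, and was highest in PCOS-like 1 over all cells too. Akr1c18 gave 40.7, 282 and 259 CPM in control and 2.68, 166 and 18.6 in PCOS-like sums. For single genes, edgeR called 0 of 7393 genes, with 279 at an unadjusted p under 0.05, and DESeq2 called 4 (Mndal, Mmp12 and Ifit2 lower, Rgcc higher), of which Mndal, Mmp12 and Rgcc were chosen after their values were seen. The interferon list was lost without PCOS-like 2 (camera adjusted p = 0.0824), with medians of -0.19 without control 1 and -1.16 without PCOS-like 1. Cell cycle was lost without control 1 (camera adjusted p = 0.524) and PCOS-like 3 (0.138), with a median of 0.90 without control 2. Collagens were lost without control 1 (camera adjusted p = 0.74) and PCOS-like 3 (0.158), with medians of 0.14, 0.93 and 0.34 without control 2, control 3 and PCOS-like 1. Follicle growth genes were lost without control 2 (camera adjusted p = 0.327), control 3 (0.223) and PCOS-like 1 (0.243), with medians of 0.57 and 0.52 without control 1 and PCOS-like 3. The follicle growth median turned to -0.31 with doublets kept and -0.06 with clusters found per library, and the call ended with doublets at the expected rate (0.07) and under the stricter cell filter (0.31). Clusters found per library ended the collagen call (-0.15), and removing the length trend moved the collagen, follicle growth and cell cycle medians to 0.68, 0.46 and 0.51. The edgeR count was 2 without control 2 or PCOS-like 1 and 1 without control 1 or PCOS-like 2, and the groups did not overlap in 8.6% of genes, where chance gives 10%.

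In the same macrophage or monocyte-like cells, H2-Eb1, which encodes the beta chain of the class II molecule H2-E (chromosome 17, mm10, 34305867 to 34316674, ENSMUSG00000060586), differed between mice more than its neighbours did. It stood at 133, 1852 and 89.0 CPM in control mice and 4132, 1317 and 2279 in PCOS-like mice, a log2 difference of 1.90 (SE 1.41, edgeR adjusted p = 0.956). Over the 7 sums where H2-Eb1 was tested, every PCOS-like library lay above every control library in 4. Its log2 differences there ran from 1.72 to 3.28 over the 7, with 0 calls by edgeR or DESeq2. The ratio of H2-Eb1 to H2-Aa UMIs was 0.0231, 0.413 and 0.0204 in control mice and 0.472, 0.411 and 0.806 in PCOS-like mice, while the largest ratio of H2-Ab1 to H2-Aa was 1.46 times the smallest. H2-Eb1, H2-Aa and H2-Ab1 were chosen after their values were seen.

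**Figure D5:**
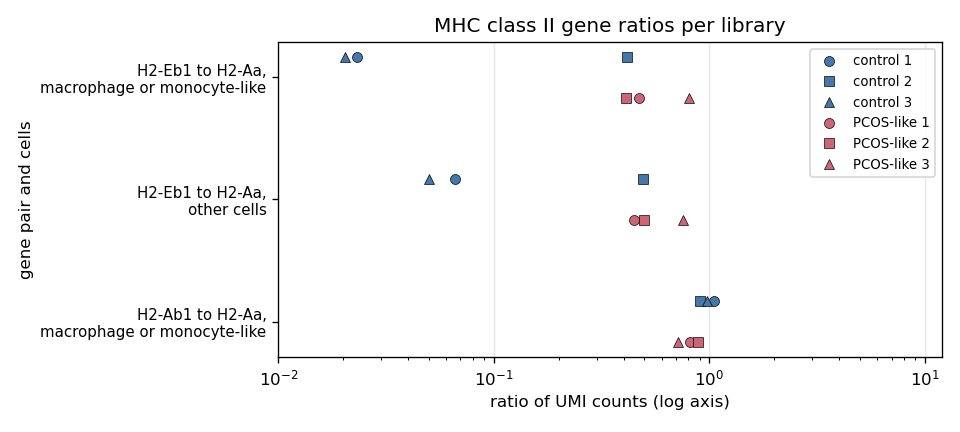
Ratios of UMI counts (log axis, horizontal) of H2-Eb1 to H2-Aa in macrophage or monocyte-like cells and in other cells, and of H2-Ab1 to H2-Aa in macrophage or monocyte-like cells (vertical axis), with 1 point per library (circle, square and triangle for mice 1, 2 and 3), blue for control and red for PCOS-like. Control 1 and control 3 lie at 0.0231 and 0.0204 for H2-Eb1 to H2-Aa, and the other 4 libraries between 0.411 and 0.806.

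T, NK or innate lymphoid-like cells showed higher respiratory chain genes (median 0.34, camera adjusted p = 9.19e-05) and ribosomal genes (median 0.43, camera adjusted p = 6.57e-06), and lower steroidogenesis genes (median -0.36, camera adjusted p = 0.0143). The adjusted p with an estimated correlation was 0.577 for these lists. Rps2 stood at 2739 ± 104 CPM in control and 4308 ± 1496 in PCOS-like mice, and Ndufa4 at 427 ± 44.1 and 696 ± 267 (SD, n = 3 each). Lymphocytes are not known to make ovarian steroids, and of the 10 steroid genes measured 2 had higher and 8 had lower values. They included Nr5a2 (log2 -0.70), Fdxr (-0.62), Cyp17a1 (0.78) and Cyp11a1 (0.18). Akr1c18 stood at 22.3, 144 and 412 CPM in control and 0, 136 and 19.7 in PCOS-like mice, and Star at 42.6, 41.9 and 236 and 10.6, 75 and 86.5. Each was lowest in PCOS-like 1 as over all cells. At the level of genes, edgeR called 0 of 4560 genes, with 350 at an unadjusted p under 0.05, and DESeq2 called 0. The steroidogenesis median turned to 0.05 without control 3 and 0.25 without PCOS-like 1, and was -0.55 and -0.58 without control 2 and PCOS-like 2, while edgeR called 1 gene without control 2, control 3 or PCOS-like 3. The steroidogenesis call also ended under the stricter cell filter (-0.30) and with clusters found per library (-0.26). No overlap of the groups was seen in 14.3% of genes, where chance gives 10%.

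The last comparison asked whether the PCOS-like effect differed between granulosa-like and stromal-like cells. Among 12570 genes measured in both, 0 passed in limma, 394 had an unadjusted p under 0.05, and the smallest adjusted p was 0.812, for Col24a1. DESeq2 was not run for this difference. Whether effects differed between other classes was not tested, so lists called in 1 class and not in another are not shown to differ.

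Without a length correction, the other lists did not pass in any of the 9 sums. Their medians ran from -0.14 to 0.17 for androgen and glucocorticoid response genes (smallest camera adjusted p = 0.238), -0.12 to 0.14 for apoptosis and p53 targets (0.415), -0.47 to 0.10 for cholesterol synthesis and uptake (0.0593), -0.09 to 0.17 for dissociation stress and immediate early genes (0.44), and -0.02 to 0.13 for ER stress (0.356). Inflammatory cytokines and NF-kB targets ran from -0.30 to 0.19 (smallest camera adjusted p = 0.0837), lipid storage and fatty acid metabolism from -0.17 to 0.12 (0.367), MHC class II and antigen presentation from -0.39 to 0.44 (0.0591), and ovulation and luteinization from -0.54 to 0.28 (0.0529). Over the 9 sums and adjusted over the list alone, MHC class II counted 4 genes higher and 1 lower, ovulation 5 higher, cell cycle 3 higher, apoptosis 1 higher and 1 lower, collagens 1 higher and 1 lower, and dissociation stress 1 higher. Over all genes tested each of these counts was 0. The lowest ovulation median, -0.54, was that of granulosa-like cells, where 17 of 20 genes were lower and the camera adjusted p was 0.0529. With the length trend removed, ovulation genes passed, lower in granulosa-like cells (median -0.58, camera adjusted p = 0.0366) and higher in stromal/theca-like cells (0.43, 0.00346), and apoptosis, cholesterol, inflammatory and MHC class II genes passed in 1 sum each. Collagens then passed in 6 sums instead of 1, interferon genes in 9 instead of 6, steroidogenesis in 3 instead of 1, and follicle growth and glycolysis genes in 2 instead of 1. Mitochondria-encoded transcripts then passed as lower in 3 sums (medians of -0.26, -0.18 and -0.18 in macrophage or monocyte-like, blood endothelial-like and T, NK or innate lymphoid-like cells), against 2 as higher before.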

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

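The removal of the transcript length trend, the leaving out of unnamed clusters and the doublets set at the expected rate in every library were chosen after seeing the data. No direction below rests on more than 3 mice per group, and classes with few cells (67 to 217 per library in T, NK or innate lymphoid-like cells) limit which genes could be tested. Of the single-gene results, 4806 kept their side of the threshold (216 with the sign of the value turned), 30 newly passed and 8 no longer passed; of the list results, 2333 kept their side (292 with the sign of the median turned), 147 newly passed (5 so turned), 149 no longer passed (2 so turned) and 15 turned direction with a call on at least 1 side; of the shares, 237 kept their side (23 with the sign turned) and 1 newly passed. Only Grk3 in smooth muscle and pericyte-like cells was called in the main fit, and all 8 single-gene losses were its own. The single-gene results that kept their side were otherwise genes not called to begin with, and no share passed in the main fit. These tallies of genes and shares therefore say little about how well a call holds. Clusters made per library left stromal/theca-like cells with too few cells to be tested.

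By DESeq2's Wald test the counts of genes were 12 in granulosa-like, 2 in theca-like, 4 in stromal-like, 37 in stromal/theca-like, 4 in smooth muscle and pericyte-like, 2 in blood endothelial-like and 4 in macrophage or monocyte-like cells and 46 over all cells. Without a count filter edgeR called 3 genes in theca-like, 158 in stromal/theca-like, 29 in smooth muscle and pericyte-like, 23 in blood endothelial-like, 28 in macrophage or monocyte-like and 20 in T, NK or innate lymphoid-like cells. With clusters made per library it called 142 in stromal-like and 0 in smooth muscle and pericyte-like cells, and 5 lists passed in granulosa-like cells. With doublets kept, 5 lists passed in granulosa-like, 3 in theca-like and 4 in stromal/theca-like cells, and edgeR called 0 genes in smooth muscle and pericyte-like and 2 in T, NK or innate lymphoid-like cells. At a Leiden resolution of 0.5, 3 lists passed in theca-like and 4 in stromal/theca-like cells and 0 genes in smooth muscle and pericyte-like cells. Under the stricter cell filter 2 lists passed in theca-like cells, and with doublets at the expected rate 5 in granulosa-like cells. With an estimated correlation and with fry, which tests whether a list's genes move one way on balance without setting them against other genes, 0 lists passed in each of the 9 sums. With the length trend removed 8 lists passed in granulosa-like, 1 in theca-like, 3 in stromal/theca-like, 8 in blood endothelial-like and 9 in T, NK or innate lymphoid-like cells. The cause was not tested for any of these. The adjusted p of Grk3 was 0.0587 with doublets kept, 0.645 at Leiden 0.5 and 0.946 with clusters made per library, within a range over all alternatives of 3.3e-06 to 0.946.

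Leaving out 1 library gave 0 to 1 changed genes in granulosa-like, theca-like, stromal-like, smooth muscle and pericyte-like and T, NK or innate lymphoid-like cells, 0 to 36 in stromal/theca-like, 0 to 3 in blood endothelial-like and 0 to 2 in macrophage or monocyte-like cells, 0 to 0 over all cells and for the difference between classes, and 0 to 1 changed shares. Lists passing ran from 4 to 8 in granulosa-like, blood endothelial-like and macrophage or monocyte-like cells, 3 to 4 in theca-like, 3 to 5 in stromal-like, 1 to 6 in stromal/theca-like, 3 to 8 in smooth muscle and pericyte-like and 3 to 6 in T, NK or innate lymphoid-like cells, and 3 to 9 over all cells.

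Some called lists turned direction, by their median or by the direction of the test, and the cause was not tested. With the length trend removed, mitochondria-encoded transcripts stood at -0.009 in theca-like, -0.118 in smooth muscle and pericyte-like, -0.18 in blood endothelial-like and -0.177 in T, NK or innate lymphoid-like cells. With clusters made per library, steroidogenesis was -0.735 and cell cycle -0.167 in smooth muscle and pericyte-like cells, and follicle growth genes -0.061 in macrophage or monocyte-like cells. With doublets kept, cholesterol genes were -0.317 and follicle growth genes -0.305 in macrophage or monocyte-like cells. With 1 library left out, cholesterol genes ran from -0.394 to 0.144 (without control replicate 1) in granulosa-like cells, and cell cycle genes from -0.517 (without PCOS-like replicate 3) to 0.76 in blood endothelial-like cells. Without PCOS-like replicate 1 the direction of the others turned: MHC class II genes ran from -0.233 to 0.587 in blood endothelial-like and from -0.16 to 0.27 in T, NK or innate lymphoid-like cells, and steroidogenesis from -0.123 to 0.354 in macrophage or monocyte-like (median 0.154 with all libraries, where the test pointed down, so that the median kept its sign) and from -0.578 to 0.251 in T, NK or innate lymphoid-like cells.

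The replicate numbers do not pair the mice: deviations of same-numbered libraries correlated at 0.12, -0.093 and 0.021 in granulosa-like cells and 0.135, 0.027 and -0.098 over all cells, and the smallest of the 3 was negative in every sum. With the replicate number as a block the TGF-beta (median -0.227) and mitochondria-encoded (0.264) calls ended in theca-like cells, edgeR called 1 gene in granulosa-like, 1 in stromal-like, 10 in stromal/theca-like, 4 in smooth muscle and pericyte-like and 18 in blood endothelial-like cells and 2 over all cells, and 5 lists passed in granulosa-like, 3 in theca-like, 8 in blood endothelial-like and 5 in T, NK or innate lymphoid-like cells and 5 over all cells.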

Other observations

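Enho, Nts and Mfap5 were called in stromal/theca-like cells by DESeq2 and not by edgeR, and were chosen after their values were seen. Enho, which encodes the peptide adropin, had a log2 difference of 1.60 (SE 0.254, edgeR adjusted p = 0.198), Nts, which encodes neurotensin, 2.29 (SE 0.442, edgeR adjusted p = 0.264) and the matrix gene Mfap5 1.31 (SE 0.211, edgeR adjusted p = 0.198). DESeq2 gave each an adjusted p of 0.000236.

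The tests of single libraries, of length as part of the cause, of an alike effect in every mouse and of H2-Eb1 were chosen only after the result was seen. Nuclear respiratory chain genes were higher by camera in PCOS-like sums of all 8 classes and over all cells, with adjusted p = 0.577 to 0.988 with an estimated correlation. PCOS-like 1 alone stays open: the list passed in 9 of 9 sums without it, but at a preset correlation of 0.01 where the estimated ones were 0.334 to 0.75, and PCOS-like 2 (0.09) lay below control 2 (0.13) over all cells. Transcript length as the whole cause stays open as well, since the passes in 6 of 9 sums after its trend was removed, which the bound set beforehand counted, rest on the same preset correlation. The call ended, as the medians became smaller, in theca-like (0.34 before and 0.07 after, quartiles 0.03 and 0.19 after), stromal/theca-like (0.45 and 0.11, quartiles 0.04 and 0.22) and macrophage or monocyte-like cells (0.28 and 0.12, quartiles -0.02 and 0.22), though the median shrank as far in some sums that kept it (0.45 to 0.13 in blood endothelial-like cells). Length as part of the cause stays open too, although the median was smaller by more than 50% after the correction in 8 of 9 sums. Removing the trend shrinks the median of any list whose genes lie along it, whatever made the trend, so the shrinkage cannot decide this. The medians before came from edgeR fold changes and those after from group means of log2 CPM. How much of the shrinkage that change of measure made was not tested. An effect of DHEA alike in every mouse stays open, since every PCOS-like library lay above every control in 2 of 9 sums only.

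Interferon response genes were lower by camera in PCOS-like sums of 5 classes and over all cells, with adjusted p = 0.596 over all cells and 0.639 to 0.988 in the classes with an estimated correlation. Without control 1 the list passed in 3 of these 6 sums and without PCOS-like 2 in 2, so either mouse may carry part of the pattern, and the 6 libraries are too few to decide. Less RNA of immune cells stays open as well, since immune markers fell by more than the list in 1 of 4 sums, with marker medians of 0.23 in theca-like, 0.25 in stromal-like, -0.159 in smooth muscle and pericyte-like and -0.72 in blood endothelial-like cells. An effect of DHEA on interferon genes was not separated from either.

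H2-Eb1 in macrophage or monocyte-like cells was low in control 1 and control 3. Fewer cells with MHC class II are argued against, because the ratio of H2-Eb1 to H2-Aa differed 39.5-fold between libraries while that of H2-Ab1 to H2-Aa differed 1.46-fold. An inherited difference between mice of this outbred stock stays open, since no genotype was read and the treatment splits nearly the same way. The ratio also differed 15.1-fold in cells outside the class, but free RNA of macrophages would carry the same ratio there, so this gives no independent support.

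The 6 libraries can be grouped into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For gene lists, the real value and the highest of the other groupings were 3 and 12 over all cells, 5 and 7 in blood endothelial-like, 3 and 10 in granulosa-like, 6 and 11 in macrophage or monocyte-like, 6 and 7 in smooth muscle and pericyte-like, 3 and 14 in stromal-like, 1 and 10 in stromal/theca-like, 3 and 7 in T, NK or innate lymphoid-like and 5 and 9 in theca-like cells. Counting the real one, groupings with a result as large numbered 10 over all cells and in granulosa-like, stromal-like and stromal/theca-like cells, 8 in T, NK or innate lymphoid-like, 7 in macrophage or monocyte-like, and 6 in blood endothelial-like, smooth muscle and pericyte-like and theca-like cells. The grouping of control 1, control 3 and PCOS-like 1 gave the 12 lists over all cells, and that of control 1, control 2 and PCOS-like 1 the 14 in stromal-like cells, several times the real count. Whether a structure of the samples made these counts was not tested. The preset correlation of 0.01 also lies far below estimated ones (up to 0.825), and its share in these counts was not tested. For genes, the real count and the highest other were 1 and 0 in smooth muscle and pericyte-like cells, where 1 grouping, the real one, was as large. They were 0 and 2 in blood endothelial-like, 0 and 3 in macrophage or monocyte-like and theca-like, 0 and 1 in stromal-like, and 0 and 0 in granulosa-like, stromal/theca-like and T, NK or innate lymphoid-like cells and over all cells. For the difference between granulosa-like and stromal-like cells they were 0 and 1, and for shares 0 and 0, with all 10 groupings, the real one included, as large in each of these.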
